A study of Caenorhabditis elegans with 4 samples.

How the data were processed

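HLH-30 binding was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in Caenorhabditis elegans hermaphrodites at the L4 larval stage. Per the labels' protocols, synchronized worms were grown at 20 °C on bacterial lawns to the wanted stage and crosslinked with 2% formaldehyde, and chromatin carrying the GFP-tagged factor was collected with anti-GFP antibodies. The series holds 4 libraries, namely 2 ChIP libraries and 2 input libraries made from chromatin that was not immunoprecipitated. The input libraries are not analysed here, because each of the 3 lists used holds peaks and none holds read counts.

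The 3 peak lists were 1 list for each ChIP replicate and 1 combined list for the series. Per the file headers, coordinates are on genome build WormBase WS180 in GFF version 3, and the lists name PeakSeq as the caller in each line. The version of PeakSeq, the aligner, the read filters, the control used for each call and the way in which the replicates were combined are not given in the sources used here. The only value deposited for each peak is a q-value, the caller's p-value adjusted for multiple testing. No fold enrichment, height, summit or read count accompanies it, so the depth of each library is unknown and no interval for the strength of a single peak can be given. The q-value depends on the number of reads in the interval as well as on enrichment, so wider peaks and more deeply sequenced libraries give smaller q-values. The deposited threshold lay near a q-value of 0.000138 in replicate 1, 0.000136 in replicate 2 and 0.000205 in the combined list, judged from the largest q-value in each. Neighbouring peaks of a list lay at least 200 bp apart in the combined list, 203 bp apart in replicate 1 and 210 bp apart in replicate 2.

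Peaks were ranked by q-value, and strength is given as −log10 q, computed here from the deposited values. Peaks were counted as shared where they overlapped by at least 1 bp. The share of replicate 1 peaks found in replicate 2 was tested against 100000 random circular shifts of the replicate 2 list within each chromosome, which keep the number, width and spacing of the peaks (one-sided). Each replicate 1 peak was paired with the strongest replicate 2 peak that it overlapped, and Spearman's and Pearson's correlations of −log10 q were tested with 100000 permutations of the pairing (two-sided). These tests run across peaks, which are not independent replicates. Peaks per chromosome were compared with chromosome length by a chi-square test and, per chromosome, by an exact binomial test (two-sided) with Benjamini-Hochberg adjustment over the 6 chromosomes. No chromosome lengths of this build were used here, so length was taken as the last peak end on the chromosome in any of the lists, and it is a lower bound. Shares carry 95% Wilson intervals and a share of 0 carries the limit that 3 counts would give, and both cover counting error only. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

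The functions were tested on simulated data. With 70% of 1527 peaks planted in both lists, 70.6% were recovered, and 2% of 100 pairs of unrelated lists of 300 peaks gave p under 0.05. A planted Pearson correlation of 0.6 over 1282 pairs came back as 0.59. A density on chromosome III planted at 1.5 times that of the other chromosomes came back as 1.53 among 2791 peaks.

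The tests, the rule for named peaks and the alternatives were fixed before the data were examined, with the following exceptions. Rank agreement by peak width and clusters of peaks counted once were added after seeing the data. So were the tests of peak spacing, position along the chromosome and q-value scale. The exact binomial tests of chromosomes other than X, and the adjustment over all chromosomes, were not in the plan either. The named peaks are the 25 combined peaks with the smallest q-values among those overlapping a peak of both replicates, and other peaks named in the text were chosen after their values were seen. Of the planned analyses, 5 needed a genome sequence or gene annotation of build WS180. They covered distance to transcription starts, E-box content, E-box content by rank, gene lists and gene biotypes. They are not reported, because no sequence or annotation of that build was used here and coordinates of different builds were not mixed. Peaks are therefore named by coordinate and not by gene. The transgene carries the hlh-30 and unc-119 loci, and whether any peak lies at them could not be told. Alternatives tried were a stricter q-value threshold, other definitions of overlap, the peaks found in both replicates, each replicate's own list, and clusters of peaks counted once.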

Results

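The binding sites of HLH-30 were mapped in L4 hermaphrodites of a strain carrying an hlh-30 transgene tagged with GFP. HLH-30 is a basic helix-loop-helix leucine zipper transcription factor, the worm counterpart of mammalian TFEB, which is known for its control of autophagy and lysosome genes. The question put by the design was where in the genome the factor binds in vivo at this stage. Peaks were called in each of 2 ChIP replicates and in a combined list. The lists give a q-value per peak and no read counts, so the depth behind each peak is unknown.

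HLH-30 peaks were found on all 6 chromosomes in every list. Replicate 1 held 1527 peaks and replicate 2 held 1559, giving 1543 ± 22.6 peaks per replicate (SD, n = 2). The combined list held 2791 peaks, 1.81 times the replicate mean. Peaks were narrow, with a median width of 531 bp in replicate 1, 538 bp in replicate 2 and 519 bp in the combined list, and the combined peaks covered 2.05 Mb, or 2.05% of the chromosomes. A minority were broad. In the combined list 121 peaks exceeded 2000 bp, against 50 in replicate 1 and 55 in replicate 2. Broader peaks were stronger, with Spearman's rho between width and −log10 q of 0.53 across combined peaks and 0.49 across the peaks of each replicate (permutation p = 1e-05 in each list, the smallest that 100000 permutations can give).

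The strongest region in the combined list lay on chromosome II from 10541852 to 10557757 (WS180). It was also the widest peak, at 15906 bp, with q = 6.88e-293. It held 5 peaks of replicate 1, the strongest at rank 3, and 4 of replicate 2, the strongest at rank 6. A further peak among the 25 strongest began just beyond it, from 10558232 to 10560041 (q = 1.81e-109). The second region lay on chromosome I from 7079029 to 7086179 (q = 2.10e-220), and its strongest partners ranked 7 in replicate 1 and 3 in replicate 2. The third lay on chromosome X from 16929311 to 16931997 (q = 9.08e-216), and this 2687 bp interval ranked 2 in replicate 1 and 1 in replicate 2.

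A second part of chromosome X held 3 of the 9 strongest peaks within a short stretch. These ran from 6735260 to 6739922 (q = 3.89e-177), from 6740186 to 6745927 (q = 2.75e-206) and from 6748755 to 6750724 (q = 9.46e-156). In replicate 1 the first pair formed a single peak, the strongest of that list, with −log10 q = 185.5. On chromosome V, the regions from 6222768 to 6231186 and from 5838415 to 5846900 were 8419 and 8486 bp wide, with −log10 q of 202.5 and 160.5. Their strongest partners ranked 15 and 6 in replicate 1, and 13 and 15 in replicate 2. The strongest peak on chromosome IV ran from 2601806 to 2604446 (q = 5.45e-160) and ranked 5 in both replicates. On chromosome III the strongest peak, from 10758883 to 10759824 (q = 4.02e-139), was the narrowest of the 25 at 942 bp and ranked 4 in both replicates.

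The 25 named peaks, chosen among those overlapping a peak of both replicates, were also ranks 1 to 25 of the whole combined list. Their −log10 q ran from 105.1 to 292.2 and their median width was 3503 bp, with 20 of them over 2000 bp. Their partners ranked no lower than 74 in replicate 1 and 86 in replicate 2. Of the 25, 21 were stronger in replicate 1, counting separately the pair on X that formed a single peak there. Chromosome X held 8 of them (32%), IV and III held 3 and 2, and I, II and V held 4 each. The share on X did not pass the test against the length of X (exact binomial test, p = 0.068).

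**Figure D1:**
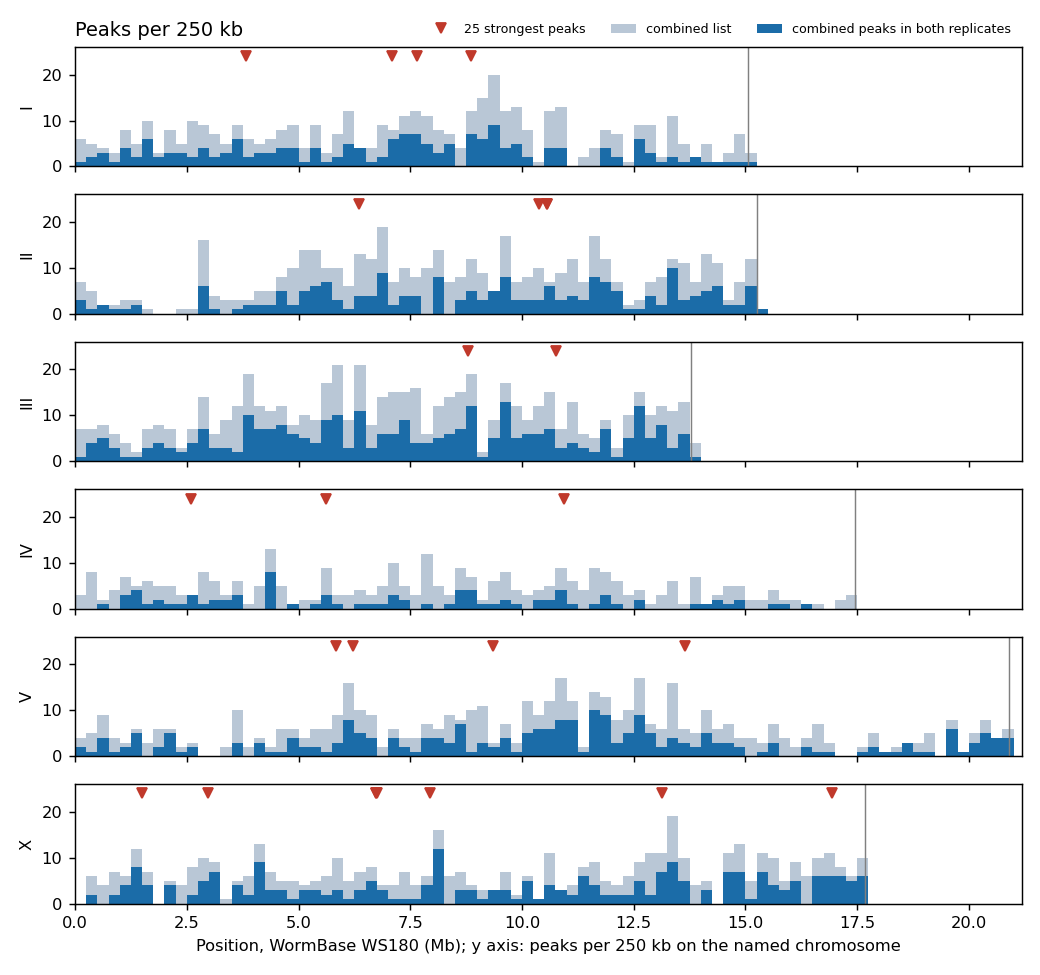
Peaks per 250 kb along each chromosome (x axis, position in Mb on WormBase WS180; y axis, number of peaks). Light bars are all 2791 combined peaks, dark bars those overlapping a peak of both replicates, triangles the 25 strongest peaks, and the grey line the last peak end; 8 triangles fall on X, 3 of them at one place near 6.74 Mb.

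The next comparison asked whether the replicates placed HLH-30 at the same sites. Of the 1527 peaks of replicate 1, 1282 (84.0%, 95% interval 82.0 to 85.7) overlapped a peak of replicate 2, and 1291 of the 1559 peaks of replicate 2 (82.8%, 80.9 to 84.6) overlapped a peak of replicate 1. Shifting one list at random along the chromosomes gave a mean of 2.38% and at most 22.0% for replicate 1 (permutation test, one-sided p = 1e-05, the smallest that 100000 shifts can give). The shared intervals amounted to 0.869 Mb, or 77.8% of the sequence in the peaks of replicate 1. Paired centres lay a median of 33.2 bp apart.

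Agreement rose with strength. In replicate 1, 305 of 306 peaks in the strongest 20% and all 305 in the next 20% had a partner in replicate 2, against 150 of 305 (49.2%, 43.6 to 54.8) in the weakest 20%. In replicate 2 the corresponding counts were 311 of 312, 309 of 312 and 157 of 311 (50.5%, 45.0 to 56.0). The 245 replicate 1 peaks with no partner had a median −log10 q of 4.56, compared with 8.73 for those with one, and the 268 unpartnered replicate 2 peaks had a median of 4.54, compared with 8.22.

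**Figure D2:**
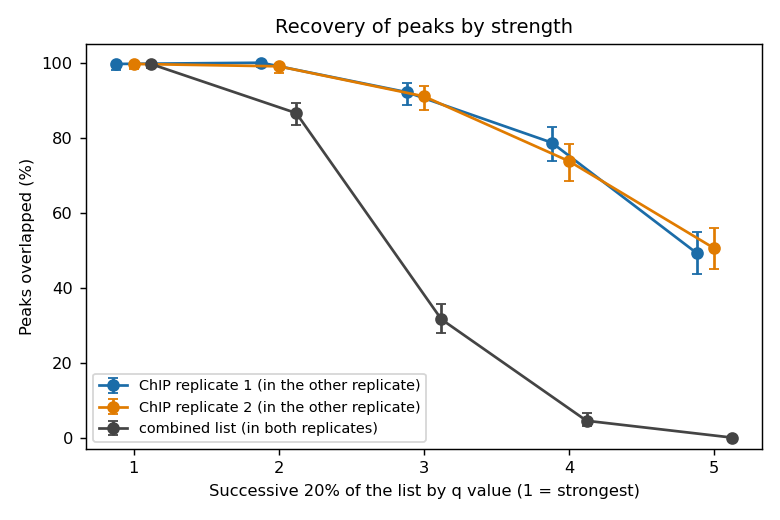
Share of peaks overlapped (y axis, percent) in each successive 20% of a list ranked by q-value (x axis, 1 is strongest), with 95% Wilson intervals and, at 0, the limit of 3 counts. Replicate peaks are counted when overlapped by the other replicate, falling to 49.2% and 50.5% in the weakest group, and combined peaks when overlapped by both, falling to 0 of 558.

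The ranking of sites was also shared. Across the 1282 pairs, −log10 q in the replicates correlated with a Spearman's rho of 0.82 and a Pearson's r of 0.93 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give), across peaks that are not independent replicates. Without the 2 pairs farthest from the median, Pearson's r was 0.94. Replicate 1 gave the smaller q-value in 742 pairs (57.9%, 55.2 to 60.6), and the median difference in −log10 q, replicate 1 minus replicate 2, was 0.47, compared with a median absolute difference of 1.74. Because width and strength were correlated, the relation was recomputed by width: rho was 0.70 in the narrower 50% of the pairs and 0.88 in the wider 50%.

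**Figure D3:**
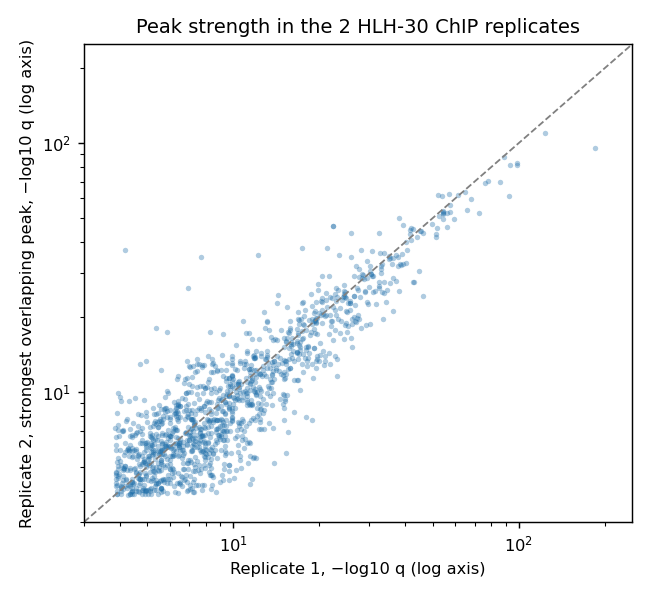
Strength of the 1282 shared peaks as −log10 q in replicate 1 (x axis, log scale) and of the strongest overlapping peak in replicate 2 (y axis, log scale), with 1 point per pair and a dashed line of equality. The points follow the line, with Spearman's rho = 0.82, and spread most widely among weak peaks.

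The combined list was then compared with the replicate lists, to show which of its sites were called in each replicate. It contained 1241 peaks (44.5%, 42.6 to 46.3) that overlapped a peak of both replicates, 232 found in replicate 1 alone, 256 found in replicate 2 alone and 1062 (38.1%, 36.3 to 39.9) found in neither. These groups differed in strength. The median −log10 q was 17.1 for peaks in both replicates, 7.16 and 7.45 for those in replicate 1 or replicate 2 alone, and 4.88 for those in neither, with median widths of 694, 453, 517 and 417.5 bp. In the strongest 20% of the combined list 557 of 559 peaks were in both replicates. In the weakest 20% none of 558 were, which allows a share of up to 0.538% (3 counts of 558, counting error only).

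Nearly all replicate peaks reappeared in the combined list, 1522 of 1527 for replicate 1 and 1553 of 1559 for replicate 2. The strongest exception was a 12598 bp peak of replicate 1 on chromosome IV from 4023744 to 4036341 (q = 8.38e-17). It was the widest peak of that list, and no combined or replicate 2 peak lay within 10 kb of it. The other 4 exceptions of replicate 1 had −log10 q of at most 4.12, and the 6 of replicate 2 had at most 5.65.

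Finally, the number of peaks on each chromosome was compared with its length. HLH-30 peaks were densest on chromosome III and sparsest on chromosome IV. The exact tests of III and IV were not planned, and these chromosomes are the extremes of the observed densities. In the replicates chromosome III carried 25.3 ± 0.616 peaks per Mb (SD, n = 2) and chromosome IV 6.71 peaks per Mb, with 117 peaks on IV in each replicate. The remaining chromosomes ranged from 14.3 ± 0.643 on V to 17.3 ± 0.88 on II. The replicate lists lacked a larger share of the combined peaks on IV than elsewhere. Their density ratios of III to IV, 3.84 and 3.71, therefore exceed the 2.34 of the combined list. In the combined list, III held 584 peaks (20.9%, 19.5 to 22.5) where its length predicts 13.8%, and IV held 316 (11.3%, 10.2 to 12.6) where its length predicts 17.4%. Both differences passed the exact binomial test after Benjamini-Hochberg adjustment, with adjusted p = 2.88e-24 for III and 1.18e-18 for IV. The counts over all 6 chromosomes departed from length in the combined list (chi-square = 182.4, 5 degrees of freedom, p = 1.67e-37), in replicate 1 (chi-square = 190.1, p = 3.73e-39) and in replicate 2 (chi-square = 173.7, p = 1.21e-35).

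Chromosome II was above its length share in the combined list, at 17.2% against 15.2% (adjusted p = 0.00723), and chromosome V below, at 18.02% against 20.87% (adjusted p = 0.000352, exact binomial test). The X chromosome, with 479 peaks (17.2%, 15.8 to 18.6), and chromosome I, with 429 (15.4%, 14.1 to 16.8), did not differ detectably from their shares of 17.66% and 15.05% (exact binomial test, adjusted p = 0.603 and 0.634). In the replicates chromosome V did not pass the exact binomial test (adjusted p = 0.126 and 0.347), and chromosome II passed in replicate 2 (adjusted p = 0.0246) but not in replicate 1 (adjusted p = 0.176). The excess on II lay in the weaker 50% of the combined list, at 19.1% (adjusted p = 0.000244), and was not detected in the stronger 50%, at 15.3% (adjusted p = 0.940), or among peaks in both replicates, at 16.4% (adjusted p = 0.284, exact binomial test), so no direction is called for II. Chromosome V was below its share in the stronger 50% (17.6%, adjusted p = 0.00392) and the weaker 50% (18.5%, adjusted p = 0.0445) but not detectably among peaks in both replicates (19.2%, exact binomial test, adjusted p = 0.228).

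Peaks occur in groups and are not independent, so these p-values are too small. With peaks up to 10 kb apart counted once, leaving 1626 groups, III held 18.8% (adjusted p = 1.31e-07) and IV 13.6% (adjusted p = 9.65e-05, exact binomial test). In the same exact test chromosome II then no longer passed (adjusted p = 0.169), while V did (adjusted p = 0.0376). Among the 1062 combined peaks found in neither replicate, III held 18.4% (adjusted p = 0.000162) and IV held 16.6%, which did not differ detectably from its length share (adjusted p = 0.492, exact binomial test). In this class V and X lay below their shares, at 16.9% and 14.3% (exact binomial test, adjusted p = 0.0045 and 0.00749). IV was below its share in the stronger 50% of the combined list, at 11.1% (exact binomial test, adjusted p = 1.73e-10). It was also below in the weaker 50%, at 11.5% (exact binomial test, adjusted p = 8.44e-09). On IV 55.7% of combined peaks were in neither replicate, against 35.8% elsewhere, which raises the share of IV in that class. The −log10 q of the replicates was also lower on IV relative to the combined list. Among combined peaks with −log10 q of at least 20 and a single partner in each replicate, the replicate value was a median 0.406 of the combined value on IV (44 peaks, bootstrap 95% interval 0.391 to 0.421) and 0.511 on the other chromosomes. Chromosome I was low too, at 0.449 (0.432 to 0.483), and the remaining 4 lay between 0.518 and 0.532.

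**Figure D4:**
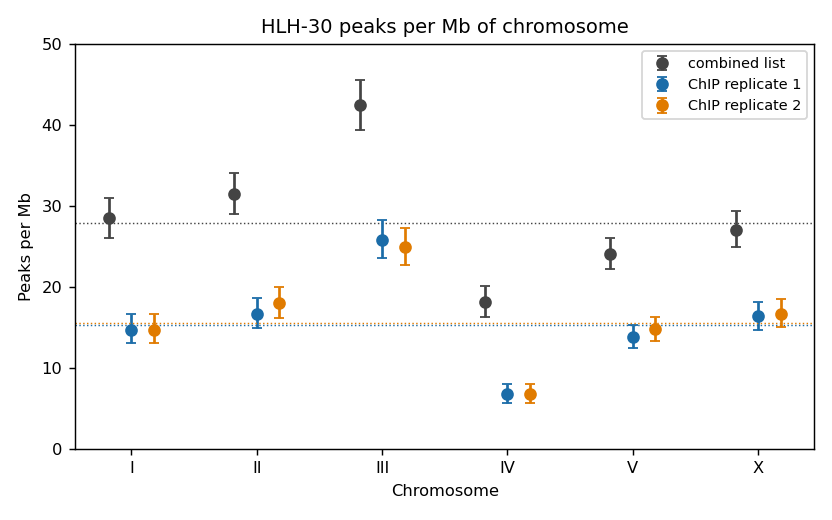
Peaks per Mb (y axis) on each chromosome (x axis) in the combined list and the 2 replicate lists, with 95% Wilson intervals scaled to density and dotted lines at each list's mean over all chromosomes. Chromosome III stands above and IV below the mean in all 3 lists, with 42.4 and 18.1 peaks per Mb in the combined list.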

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

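Rank agreement by width and the grouping of neighbouring peaks were alternatives chosen after seeing the data. Across 29 alternatives for 10 results, 21 kept the direction and the side of the threshold, or the size of a count. The overlap of replicate 1 with replicate 2 was 83.9% with 50% of the shorter peak covered, 74.9% with centres within 200 bp and 82.3% between the stronger 50% of each list, each with permutation p = 1e-05. Spearman's rho ranged from 0.70 to 0.88. Keeping the stronger 50% left by construction 1396 combined peaks, 764 in replicate 1 and 780 in replicate 2, and it lowered the combined peaks found in neither replicate from 1062 to 58. The X chromosome changed side around its length share of 17.7%, with 17.2% in the combined list, 18.5% in its stronger 50% and 19.4% among peaks in both replicates. With 1 replicate left out, the share is that of the other replicate's own list, 18.92% in replicate 2 and 18.93% in replicate 1. None of these shares of X passed the exact binomial test (unadjusted p from 0.109 to 0.503). Among peaks in neither replicate X passed it and lay below its share, at 14.3% (adjusted p = 0.00749, exact binomial test). No direction is called for X as a whole, and the cause was not tested. Chromosomes III and IV kept their direction and passed the test in the combined list, its stronger 50%, the peaks in both replicates and each replicate's list. They also did so with peaks up to 10 kb apart counted once. Over these settings they held 18.8% to 23.4% and 7.01% to 13.6% of peaks. Among peaks in neither replicate III passed at 18.4% (adjusted p = 0.000162), but IV did not, at 16.6% (adjusted p = 0.492, exact binomial test). Overlap between replicates has no value with a replicate left out. No paired analysis was possible because the input libraries, which share replicate numbers with the ChIP libraries, have no peak list among the files used here. A further 31 settings for the 5 analyses that needed a genome sequence or annotation were not run. The lists give no depth, so whether a site that is missing from 1 replicate is unbound there cannot be read from them.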

Other observations

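The tests in this part were chosen after the results were seen, except the distance of combined-only peaks to replicate peaks and the density ratio in the stronger 50% of the list. HLH-30 peaks were not spread evenly along the chromosomes. On the autosomes 43.5% of combined peak centres fell in the central part of the chromosome, from 33.3% to 66.7% of its length, which is known to be rich in genes, with 48.5% on V (95% Wilson interval 44.2 to 52.9), 44.0% on II, 43.6% on I, 40.6% on III and 40.2% on IV. On X the share was 29.0% (25.1 to 33.2). The difference of 14.5 percentage points between autosomes and X exceeded that of rotated lists (SD 5.19, permutation test over 10000 rotations, two-sided p = 0.0024). Over all chromosomes the central part held 41.0% of combined peaks against 33.4% after rotation (permutation test, p = 0.0052), 40.4% in replicate 1 (p = 0.0277) and 42.1% in replicate 2 (p = 0.0094).

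Peaks also lay close to one another. A neighbour within 5 kb was present for 50.3% of combined peaks, against a mean of 25.2% and at most 28.8% in 1000 random placements with the same number of peaks per chromosome (permutation test, one-sided p = 0.001, the smallest they can give). Replicate 1 gave 43.2% against 15.2%, replicate 2 gave 45.2% against 15.4%, and combined peaks in both replicates gave 38.6% against 12.6%. The random placements were uniform along each chromosome. They keep neither the crowding of peaks in the central part of the autosomes nor broad regions called as several peaks. How much of the difference comes from either was not tested, so it does not by itself show local grouping of separate sites. Joining peaks up to 10 kb apart placed 1786 of the 2791 peaks in 621 groups and left 1005 alone. The most crowded groups held 9 peaks each, and there were 5 of them. The one with the strongest peak ran on chromosome V from 6213422 to 6247922, and others lay on chromosome I from 7466578 to 7501003 and on chromosome II from 6822198 to 6849713.

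Chromosome IV stood apart in how often combined peaks were missing from the replicates. On IV 55.7% of combined peaks (50.2 to 61.1) were in neither replicate, against 35.8% elsewhere (Fisher's exact test, adjusted p = 1.16e-10). Larger combined q-values on IV do not account for this. At matched combined q-values 121.2 such peaks were expected with an SD of 5.46, and 176 were seen (permutation test, adjusted p = 0.0006). IV held 31 of the 58 such peaks in the stronger 50% of the list. The matching takes combined q-values as comparable between chromosomes, which could not be checked, so weaker binding on IV is not excluded. A candidate explanation is a chromosome-wide scale of the q-values that differs between the replicate lists and the combined list. The ratio of the values cannot tell which of the lists is affected. Among strong peaks found in both replicates the replicate −log10 q was a median 0.406 of the combined value on IV against 0.511 elsewhere (permutation test, adjusted p = 0.0003), and chromosome I was also low at 0.449. Matched again without IV, whose excess raises the expectation of the others, I had 176 peaks in neither replicate where 159.0 were expected (SD 5.48, permutation test, adjusted p = 0.0195). This rests on replicate 2, where 215 peaks of I were missing against 193.0 expected (adjusted p = 0.0015), while in replicate 1 it did not pass, at 210 against 196.6 (permutation test, adjusted p = 0.100), so the support from I is weak. II, III, V and X, with ratios from 0.518 to 0.532, did not differ detectably from expectation for peaks in neither replicate (adjusted p from 0.79 to 0.807). What sets this scale stays open without read counts, and no biological explanation was tested.

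The excess of peaks on III over IV held under 3 technical readings. The density ratio of III to IV was 2.34 in the combined list, and it was 1.75 (95% interval 1.47 to 2.08) with neighbouring peaks counted once, 2.56 (2.11 to 3.10) in the stronger 50% of the list and 3.71 (3.01 to 4.58) in the replicate with the lower ratio. It differed between classes of combined peak, from 4.24 (3.33 to 5.38) for peaks in both replicates to 1.40 (1.14 to 1.72) for those in neither. At matched combined q-values replicate 1 lacked 203 IV peaks where 154.4 were expected, and replicate 2 lacked 202 where 151.1 were expected. This loss raises the ratio in the replicates and in the class found in both, and lowers it in the class found in neither. Dense groups, weak peaks near the threshold or a single replicate do not account for the excess on III alone. A chromosome-wide scale in the combined list cannot be told apart from a difference in binding, because its own scale cannot be measured without read counts. Among peaks with −log10 q of at least 20 the ratio was 2.79 (108 peaks on III and 49 on IV, 95% interval 1.99 to 3.91). With a factor of 1.26 applied to III it was 2.12 (82 peaks on III, 1.49 to 3.02, counting error only). Raising the limit on III presumes that combined values on IV are lowered by as much as the replicate values appear to be. If combined values on IV were instead too large, the ratio would move the other way. Neither direction could be checked, so 2.12 is not a corrected ratio. That factor sets all other chromosomes pooled against IV in the replicates. The replicate value on III itself was 0.523 of the combined value, above the pooled 0.511, so the factor of III alone would be somewhat larger. Gene content of the chromosomes was not tested.

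The 1062 combined peaks found in neither replicate were weak, but a looser threshold alone does not account for them, since 8.38% had a combined q-value that fails the replicate threshold of −log10 q = 3.86. Pieces of replicate peaks that were split differently were looked for by distance only. By definition these peaks overlap no replicate peak, so a piece inside a replicate peak could not be among them. Of the 1062, 10.2% lay within 1000 bp of a replicate peak, against a mean of 5.39% and at most 7.16% in 200 rotations. Most were therefore not close neighbours of a replicate peak, which is all that this distance can show. A candidate explanation is that the same site gets a smaller q-value in the combined call. At strong peaks the better replicate reached a median 0.551 of the combined −log10 q. With that ratio 88.4% of the peaks in neither replicate would fail the replicate threshold, against 46.3% of those in 1 replicate and 2.34% of those in both. The scaling is a single cut on combined −log10 q, in which the classes already differed, so the order of these shares is no evidence for the explanation. The 46.3% were called in a replicate although the ratio puts them below its threshold. The ratio is also carried from strong peaks to weak ones. Whether the combined call used more reads stays open, because how it was made is not given in the sources used here.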
